A study of Caenorhabditis elegans with 18 samples.

How the data were processed

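The data were 18 poly(A)-selected RNA sequencing libraries of whole day-1 adult worms, 12 in experiment 1 and 6 in experiment 2. The deposited tables hold raw counts per gene, 1 column per library, and the processing notes of the authors name bcl2fastq, STAR 2.5.0a, HTSeq and the genome build WBcel235. The annotation release and the strand setting that the authors used are not given in the sources used here. The values were checked to be whole numbers with a different total in each column, over 46748 gene identifiers. Each column was joined to its library by the file and column that the label of the library names.

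Gene symbols and positions came from the Ensembl 115 annotation of WBcel235. No symbol was found for 3055 identifiers, which held 1.42% of the counts. Total counts ranged from 20621965 to 29518450 in experiment 1 and from 10449794 to 16814732 in experiment 2, so that 1 CPM stood for at least 10 reads in each library. Ribosomal RNA took 1.16% to 9.86% of the counts in experiment 1 and 0.0785% to 2.04% in experiment 2. Counting error is small beside the spread between libraries only for genes well above 1 CPM. Near or below 1 CPM it adds clearly to that spread. No 2 libraries of a group had near-identical counts, as the smallest chi-square per degree of freedom was 11.0.

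Genes were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood, with TMM factors and filterByExpr at its defaults (a minimum count of 10 and a total of 15). The cold response in WT was fitted over 12 WT libraries with a term for the experiment. The other 4 comparisons were the cold response in ire-1, its difference from WT, and the strains compared in the control and in the cold. They were fitted together over the 12 libraries of experiment 1. The deposit does not say what a replicate number marks. After removing group means, WT and ire-1 libraries with the same number and condition correlated at 0.327 to 0.888, with 6 of 6 pairs above 0.1, and by that limit the numbers were taken to pair the strains within each condition. Libraries with different numbers correlated as highly outside control 1 and cold 2, such as WT control 2 with ire-1 control 3 (0.651) and WT control 3 with ire-1 control 2 (0.753), against 0.596 for control 2 of both strains. WT cold 3 with ire-1 cold 1 had 0.338, against 0.327 for cold 3 of both strains. The pairing is therefore a reading of the data and may rest on the 4 libraries with much sperm RNA. Over all 21 pairs of libraries with the same number the lowest correlation was -0.864 and only 12 were above 0.1, so control and cold libraries of a number are not paired. The planned fits have no pairing. A fit with a block for each number within each condition was added after the results of the planned fits were seen, and its value is given where it changed a call. The p-values were adjusted by Benjamini-Hochberg over the tested genes of each comparison at 0.05.

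Gene lists (43, fixed with their members before the data were examined, 10 members not found) were tested with camera in limma 3.58.1 at a correlation of 0.01, and again with an estimated correlation. Lists with at least 3 tested genes were used. Within each list the genes were also adjusted over the list alone. Genes were named by a rule: a set of genes always given (ire-1, xbp-1, hsp-3, hsp-4, fat-5, fat-6 and fat-7), the 5 largest called rises and falls with a mean of at least 10 CPM in the higher group and no overlap of single libraries within an experiment, up to 4 genes of each list with the smallest p, and members of the fatty acid and lipase lists. Any other named gene was chosen after its values were seen, and its alternatives were computed too. Correlations were made across genes. The cold score used genes called in experiment 2 alone and was tested in experiment 1 by an exact permutation test.

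The alternatives were RLE and upper-quartile factors, no filter, DESeq2 1.42.0, limma-voom, a block for the replicate number, each experiment alone, no experiment term, all 18 libraries, fits of 2 groups alone, and each library left out in turn, and for the cold score another prior count, other fold minimums and the raised or lowered genes alone. Separate fits were added after the data were seen. They left out the 4 libraries with much sperm RNA, used the sperm-gene level as a covariate, or used an indicator for those libraries. Others used the block within each condition, or left out WT control 6 and WT cold 5. Other splits of the libraries were fitted the same way, all 10 for 3 against 3 and 100 drawn with a fixed seed where there were more. For cold in WT 100 splits that keep 3 against 3 within each experiment were drawn as well.

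The procedure was tested on simulated data with the sample sizes and spread of these libraries. A 2-fold change was called in 52.2% of the changed genes for cold in WT, 7.46% for cold in ire-1, 1.49% for the difference in cold response, 4.48% for the strains in the control and 11.9% for the strains in the cold. A 4-fold change was called in 86.6%, 43.3%, 26.9%, 46.3% and 47.8%. Unchanged genes called numbered 4, 3, 1, 4 and 3, and 0 of 40 random lists passed in each comparison. Each gene was drawn independently, so the simulation lacks genes that vary together between libraries. These numbers of false calls therefore do not carry over to the real counts. Other splits of the real WT libraries gave a median of 16 lists, and at most 26. The permutation test of the cold score rejected 5% of 200 draws without a difference and 43.5% with a difference of 4 SD. These draws held no strain difference in the control. The real scores were higher in ire-1 control than in WT control, so these shares do not carry over to them. Tables were handled and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. No library was left out of the comparisons. Reads were not mapped again, since the files hold counts per gene, so splicing of xbp-1 and the extent of the deletion in ire-1 were not examined.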

Results

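RNA from whole *Caenorhabditis elegans* was sequenced after poly(A) selection, and reads were counted per gene in 18 libraries. Worms of the wild-type strain N2 (WT) and of the strain ire-1(ok799), which carries a deletion in the gene for the endoplasmic reticulum (ER) stress sensor IRE-1, were grown at 15 °C. They were taken as day-1 adults, either directly (control) or after 24 h at 2 °C (cold). Cold worms were therefore also 24 h older than control worms, and none of the 18 libraries is of worms aged without cold. Experiment 1 held 12 libraries, with n = 3 for each of WT control, WT cold, ire-1 control and ire-1 cold. Experiment 2 held 6 libraries, with n = 3 for WT control and n = 3 for WT cold. Replicates 1 to 3 are those of experiment 1 and replicates 4 to 6 those of experiment 2. Strain, condition and experiment are the labels of the deposit.

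Total counts of gene reads in experiment 1 were 24417696, 25118994 and 25886872 in WT control and 28605468, 26100941 and 26579202 in WT cold. They were 29518450, 25862209 and 24139140 in ire-1 control and 24954364, 22505966 and 20621965 in ire-1 cold. Experiment 2 was sequenced less deeply, with 14599937, 12386297 and 15778668 in WT control and 15412931, 10449794 and 16814732 in WT cold. All 18 libraries were used. In 4 libraries of experiment 1 the summed level of 53 sperm genes was 1942 CPM (normalised counts, WT control 1), 2130 (ire-1 control 1), 492 (WT cold 2) and 1691 (ire-1 cold 2), against 29.5 to 198 in the other 14. Collagen genes were also higher in each of these 4 libraries than in both others of the same group. The yolk genes took 7.001% and 5.06% of the counts in the 2 control libraries and 1.74% and 1.88% in the 2 cold libraries.

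**Figure D1:**
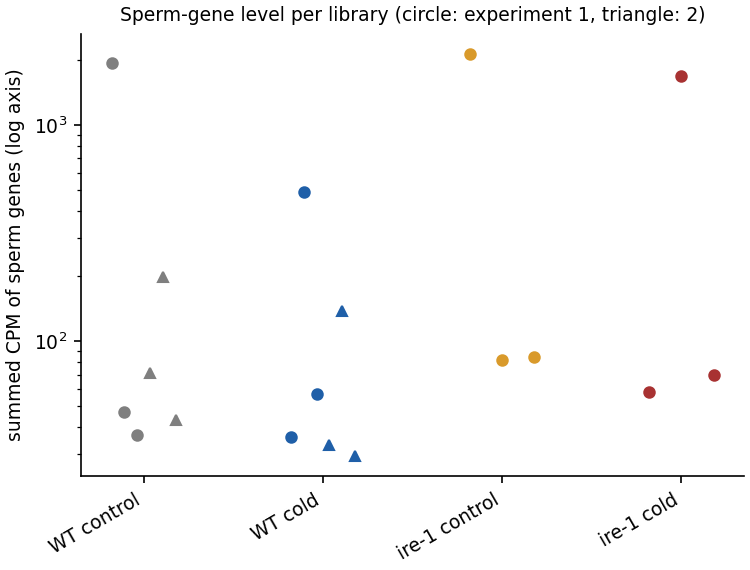
Summed level of 53 sperm genes (CPM, log axis) in each of the 18 libraries by group, with circles for experiment 1 and triangles for experiment 2. WT control 1 and ire-1 control 1 reached 1942 and 2130 CPM and WT cold 2 and ire-1 cold 2 reached 492 and 1691 CPM, while the other 14 libraries lay between 29.5 and 198.

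The ire-1 gene itself (WBGene00002147, chromosome II, 8112243 to 8124910 on WBcel235) was counted in every library. These gene-level counts pool reads inside and outside the deleted part. In WT control replicates 1 to 6 it stood at 85.4, 91.4, 173, 153, 131 and 209 CPM, and in WT cold replicates 1 to 6 at 208, 169, 183, 228, 169 and 215 CPM. It was lower in the mutant, at 36.6, 56.3 and 54.6 CPM in the control and 63.8, 39.0 and 54.1 CPM in the cold. The lowest WT library of experiment 1 (85.4 CPM) lay above the highest ire-1 library (63.8 CPM). By edgeR the log2 difference between ire-1 and WT was -1.29 ± 0.26 in the control (adjusted p = 0.149) and -1.89 ± 0.26 in the cold (adjusted p = 0.0943), with n = 3 per group, and neither passed 0.05 over all genes. With WT and ire-1 libraries of the same number paired within each condition, both passed, at -1.25 (adjusted p = 0.0133) in the control and -1.9 (adjusted p = 0.00339) in the cold. Here and below, this pairing was read from the same data and is not given by the labels, so calls that need it are tentative. Without WT control 3 and without pairing the difference in the cold passed (adjusted p = 0.0163). Within WT, cold moved ire-1 by 0.47 ± 0.17 (n = 6 per group, adjusted p = 0.0914), which passed without WT control 3 (adjusted p = 0.0324) or WT control 6 (adjusted p = 0.0399).

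**Figure D2:**
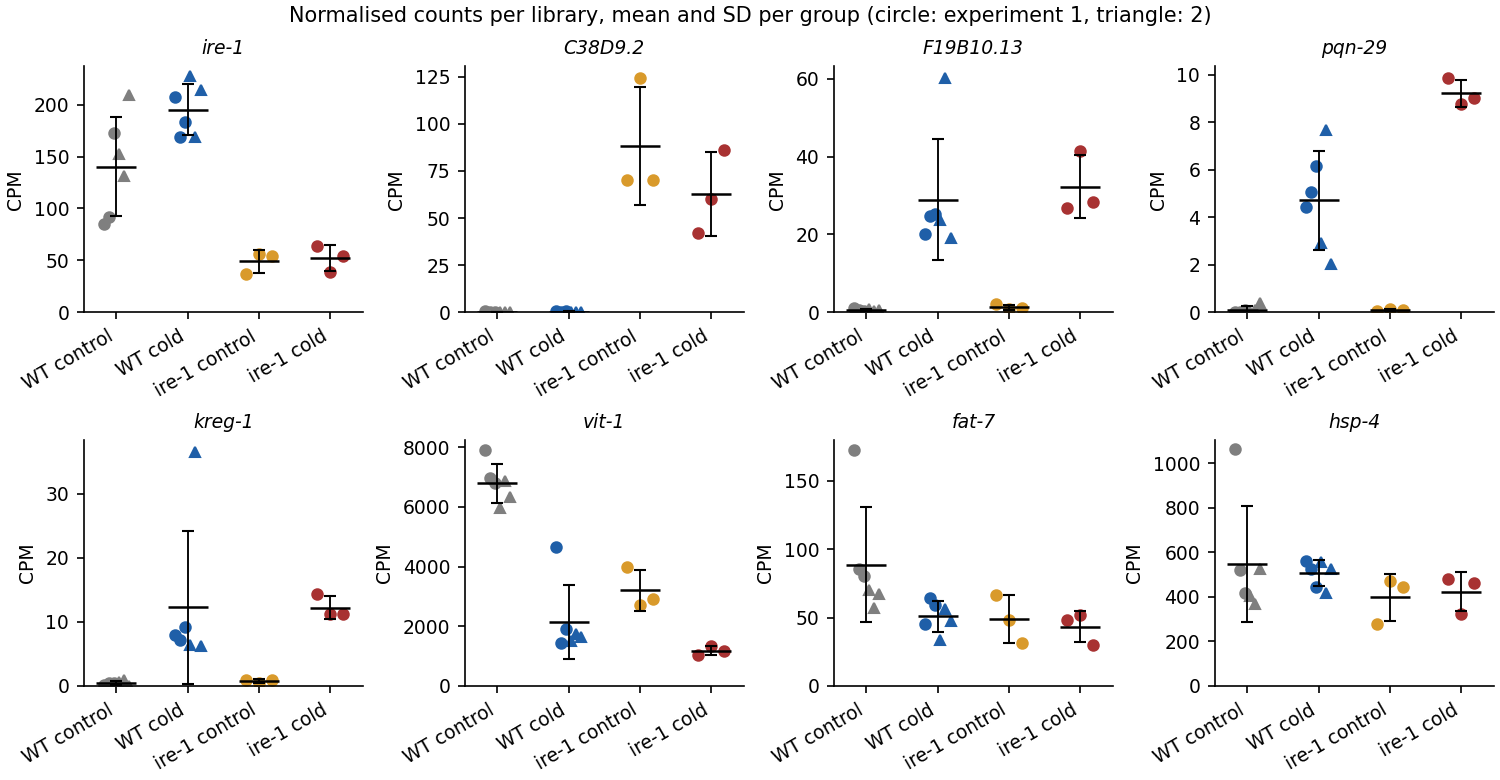
Level of 8 genes (CPM) in each of the 18 libraries by group, with circles for experiment 1, triangles for experiment 2 and the mean with its SD. The ire-1 gene lay between 36.6 and 63.8 CPM in the mutant and between 85.4 and 228 CPM in WT, and C38D9.2 lay between 42.3 and 124 CPM in the mutant and between 0 and 0.669 CPM in WT.

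The first comparison asked which genes 24 h at 2 °C changed in WT, over both experiments (n = 6 per group). All values given from here on for genes are log2 fold changes ± SE from edgeR, with the p adjusted by Benjamini-Hochberg over all tested genes. The SE, here and above, was derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F. Among genes with a mean of at least 10 CPM in the higher group and no overlap of single libraries within an experiment, the largest rises were in genes with little described function. These were F19B10.13 (5.53 ± 0.46, adjusted p = 9.29e-05), Y58A7A.4 (5.49 ± 0.43, adjusted p = 9.29e-05), C49G7.7 (5.12 ± 0.65, adjusted p = 0.000642), kreg-1 (4.73 ± 0.61, adjusted p = 0.000747) and F33H12.7 (4.32 ± 0.49, adjusted p = 0.000416), each under 1 CPM on average in the control. The genes kreg-1 and F33H12.7 reached the mean of 10 CPM only through WT cold 5. It held 36.5 CPM of kreg-1 against 6.27 to 9.21 in the other WT cold libraries, and 25.5 of F33H12.7 against 6.06 to 9.84. In experiment 1 alone, which lacks that library, the rises were 4.57 ± 0.48 for kreg-1 and 3.86 ± 0.60 for F33H12.7. F19B10.13 (WBGene00194713, chromosome II) went from 0.594 ± 0.319 to 28.7 ± 16.38 CPM (mean ± SD). The bZIP transcription factor gene zip-10 rose by 3.34 ± 0.50 (adjusted p = 0.00153), from 3.36 ± 2.68 to 34 ± 20.9 CPM. Also raised were the serpentine receptor gene srr-6 (3.71 ± 0.82, adjusted p = 0.0119), the infection-response gene irg-2 (3.00 ± 0.45, adjusted p = 0.00152), the glutathione S-transferase gene gst-24 (2.33 ± 0.51, adjusted p = 0.0110) and unc-31 (1.37 ± 0.31, adjusted p = 0.0137), which acts in the release of dense-core vesicles. The deepest falls within the same limits were F22F7.8 (-4.50 ± 0.60, adjusted p = 0.000857), anmt-3 (-4.19 ± 0.78, adjusted p = 0.00487), the aspartyl protease gene asp-13 (-3.47 ± 0.48, adjusted p = 0.00104), K06A4.7 (-3.26 ± 0.54, adjusted p = 0.00256) and the glucuronosyltransferase gene ugt-63 (-3.22 ± 0.50, adjusted p = 0.00195). Without WT control 1, where F22F7.8, anmt-3 and ugt-63 stood above all other WT controls, all 5 still passed, with smaller falls of -3.70 for F22F7.8, -3.04 for anmt-3 and -2.60 for ugt-63. In experiment 2 alone F22F7.8 had -3.64 ± 0.45, anmt-3 -3.19 ± 0.66 and asp-13 -3.51 ± 0.72, so the place of anmt-3 above asp-13 rests on that library. The transcript of asp-13 went from 155 ± 29.7 to 14.1 ± 11.8 CPM. Other falls were sams-1 (-3.09 ± 0.51, adjusted p = 0.00256), an S-adenosylmethionine synthetase gene, atf-4 (-2.45 ± 0.37, adjusted p = 0.00160), a bZIP factor of the stress response to amino acid shortage, and bas-1 (-1.80 ± 0.26, adjusted p = 0.00138), an aromatic amino acid decarboxylase gene.

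Yolk genes and some lists of fat metabolism moved down in WT cold. All 6 vitellogenin genes, which encode yolk proteins, fell (6 adjusted over the list alone), with vit-1 (-1.75 ± 0.24, adjusted p = 0.000896) at 6883 ± 946 CPM in the control and 2096 ± 1129 CPM in the cold. The near-identical copies vit-3, vit-4 and vit-5 share reads, so their single values are uncertain. Of 21 genes of peroxisomal beta-oxidation 12 fell (16 fell and 1 rose adjusted over the list alone), with a median of -1.50. Among them were the thiolase gene daf-22 (-2.29 ± 0.33, adjusted p = 0.00133) and the acyl-CoA oxidase genes acox-3 (-2.0 ± 0.29, adjusted p = 0.00138), acox-1.1 (-1.60 ± 0.24, adjusted p = 0.00160) and acox-1.4 (-1.89 ± 0.29, adjusted p = 0.00160). Of 27 genes of mitochondrial beta-oxidation 8 fell (15 fell and 2 rose adjusted over the list alone), such as ech-7 (-1.84 ± 0.15, adjusted p = 9.29e-05), hacd-1 (-1.46 ± 0.25, adjusted p = 0.00324) and cpt-5 (-2.18 ± 0.41, adjusted p = 0.00523). Of 17 fatty acid desaturases and elongases 7 fell (11 adjusted over the list alone), and all 17 values lay below 0. The elongase genes elo-6 (-2.09 ± 0.34, adjusted p = 0.00229), elo-5 (-1.99 ± 0.42, adjusted p = 0.00928) and elo-2 (-0.93 ± 0.17, adjusted p = 0.00385) were the lowest in p. The delta-9 desaturase genes fell narrowly past the threshold, fat-5 (-1.07 ± 0.30, adjusted p = 0.0358), fat-6 (-1.26 ± 0.33, adjusted p = 0.0280) and fat-7 (-0.80 ± 0.24, adjusted p = 0.0447). The call of fat-6 was lost without WT cold 1, 3, 4 or 6 or WT control 4 or 5, up to an adjusted p of 0.0755. The call of fat-5 was lost without WT control 1, 4 or 5 or WT cold 1, 2, 3 or 4 (up to 0.0871), and that of fat-7 without WT control 1, 4 or 5 or WT cold 1, 2, 3, 4 or 6 (up to 0.109). Since fat-6 and fat-7 are close paralogs, their separate values are uncertain. The gene for the sterol regulatory element-binding protein also fell, sbp-1 (-1.95 ± 0.22, adjusted p = 0.000416). By camera these 4 lists had adjusted p = 7.26e-07 (yolk), 6.44e-09 (peroxisomal), 0.000417 (mitochondrial) and 7.47e-05 (desaturases and elongases), and each had an adjusted p = 0.582 with an estimated correlation. Lipid-binding proteins lost 4 of 18 genes (7 adjusted over the list alone), such as lbp-6 (-1.08 ± 0.18, adjusted p = 0.00256), with an adjusted p = 0.00219 and an adjusted p = 0.854 with an estimated correlation. Other fat lists did not pass by camera: fatty acid synthesis and lipid transcription factors (median 0.09, adjusted p = 0.985), triglyceride synthesis (0.03, 0.911), lipases (-0.25, 0.494) and phospholipid synthesis (-0.47, 0.356).

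Several lists of defence, detoxification and gut genes moved the same way in WT. Of 64 C-type lectins 26 fell (34 adjusted over the list alone), such as clec-265 (-2.47 ± 0.24, adjusted p = 0.000249), clec-4 (-2.23 ± 0.28, adjusted p = 0.000630) and clec-56 (-2.38 ± 0.30, adjusted p = 0.000642). Of 52 antimicrobial peptides and lysozymes 11 fell (24 fell and 2 rose adjusted over the list alone), such as lys-1 (-2.01 ± 0.38, adjusted p = 0.00500), ilys-5 (-2.01 ± 0.34, adjusted p = 0.00288) and lys-8 (-1.57 ± 0.34, adjusted p = 0.0105). Of 49 UDP-glucuronosyltransferases 19 fell (30 adjusted over the list alone), such as ugt-17 (-2.65 ± 0.39, adjusted p = 0.00145) and ugt-62 (-1.27 ± 0.20, adjusted p = 0.00223). Of 44 cytochrome P450s 17 fell (22 adjusted over the list alone), such as cyp-29A4 (-2.18 ± 0.31, adjusted p = 0.00117) and cyp-25A1 (-1.67 ± 0.26, adjusted p = 0.00183). Intestine markers fell in 8 of 15 genes (11 adjusted over the list alone), among them the peptide transporter gene pept-1 (-2.13 ± 0.24, adjusted p = 0.000414), the proton pump subunit gene vha-6 (-1.64 ± 0.30, adjusted p = 0.00469), the microvillar actin gene act-5 (-1.54 ± 0.32, adjusted p = 0.00823) and the gut esterase gene ges-1 (-1.79 ± 0.42, adjusted p = 0.0168). Outputs of the insulin pathway fell in 5 of 19 genes (9 adjusted over the list alone), such as dod-3 (-3.0 ± 0.38, adjusted p = 0.000632) and icl-1 (-2.38 ± 0.56, adjusted p = 0.0166). Camera gave adjusted p = 7.64e-11 for the C-type lectins, 4.60e-06 for the P450s and 2.21e-06 for the intestine, and each of these 3 had an adjusted p = 0.582 with an estimated correlation. It gave 6.44e-09 for the UDP-glucuronosyltransferases and 0.000389 for the insulin outputs, both with an adjusted p = 0.728 with an estimated correlation. The antimicrobial list had an adjusted p = 2.14e-05 and an adjusted p = 0.918 with an estimated correlation. The infection reporters (adjusted p = 0.224), the intracellular pathogen response (0.356), glutathione and oxidative stress (0.281, with 17 of 45 values above 0) and metal homeostasis (0.0519) did not pass.

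Collagens fell in 12 of 82 genes (16 fell and 1 rose adjusted over the list alone), with 81 of 82 values below 0, and included col-10 (-2.77 ± 0.45, adjusted p = 0.00233), dpy-2 (-2.24 ± 0.34, adjusted p = 0.00160) and sqt-3 (-1.93 ± 0.32, adjusted p = 0.00271). These genes were high in the 4 libraries with much sperm RNA. Neuropeptides fell in 3 of 72 genes (1 adjusted over the list alone), such as flp-34 (-1.84 ± 0.26, adjusted p = 0.00107). Among 34 germline and oocyte markers the synapsis gene syp-1 (0.58 ± 0.14, adjusted p = 0.0199) rose (1 adjusted over the list alone), a call that was lost without WT control 4 (adjusted p = 0.0534) or 5 (adjusted p = 0.0559). None of 33 proteasome subunits passed by edgeR (0 adjusted over the list alone), but all 33 lay above 0 with a median of 0.17, such as rpn-8 (0.35 ± 0.12, adjusted p = 0.0731) and rpn-3 (0.38 ± 0.14, adjusted p = 0.0974). Without WT control 6 both rpn-8 (adjusted p = 0.0467) and rpn-3 (adjusted p = 0.0411) passed by edgeR. By camera the adjusted p was 8.05e-05 for collagens, 0.000482 for neuropeptides, 0.000806 for the germline list and 0.00233 for the proteasome, and each had an adjusted p = 0.918 with an estimated correlation. The germline list did not pass without WT control 1 (adjusted p = 0.0918). ER chaperones and ER stress sensors did not pass (adjusted p = 0.833 and 0.858), and hsp-3 (-0.64 ± 0.27, adjusted p = 0.132), hsp-4 (-0.14 ± 0.24, adjusted p = 0.707) and xbp-1 (0.15 ± 0.21, adjusted p = 0.627) did not pass either. The 7 stress sensors had a median of 0.15 but a mean of -0.20, and their test pointed up. Cold survival genes did not pass as a list (adjusted p = 0.338), with a median of -0.05, a mean of 0.32 and 2 of 18 genes raised (2 adjusted over the list alone).

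In all, edgeR called 1545 of 11766 genes in WT, of which 318 rose and 1227 fell, and 1194 changed at least 2-fold. Camera called 15 of 42 lists, 2 up and 13 down, and 0 with an estimated correlation. The median of all genes was -0.07 with TMM scaling and -0.18 with upper-quartile factors, so values up to that size are within the scaling. Experiment 1 alone gave 3 genes and experiment 2 alone 48, and all 48 had the same sign in experiment 1. Across 11250 genes, which are not independent replicates, the experiments had r = 0.826 and rho = 0.824. No gene was called for a different cold response between the experiments (edgeR, 0 genes, 71 at an unadjusted p under 0.05). With n = 3 per group in each experiment, the lack of a call does not show that the responses were equal. Leaving out 1 library moved the count to 867 (WT cold 1), 987 (WT cold 3), 886 (WT control 4), 892 (WT cold 4), 848 (WT control 5), 966 (WT cold 6) or 2632 (WT control 6). Without WT control 6 and WT cold 5 together it was 3395.

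**Figure D3:**
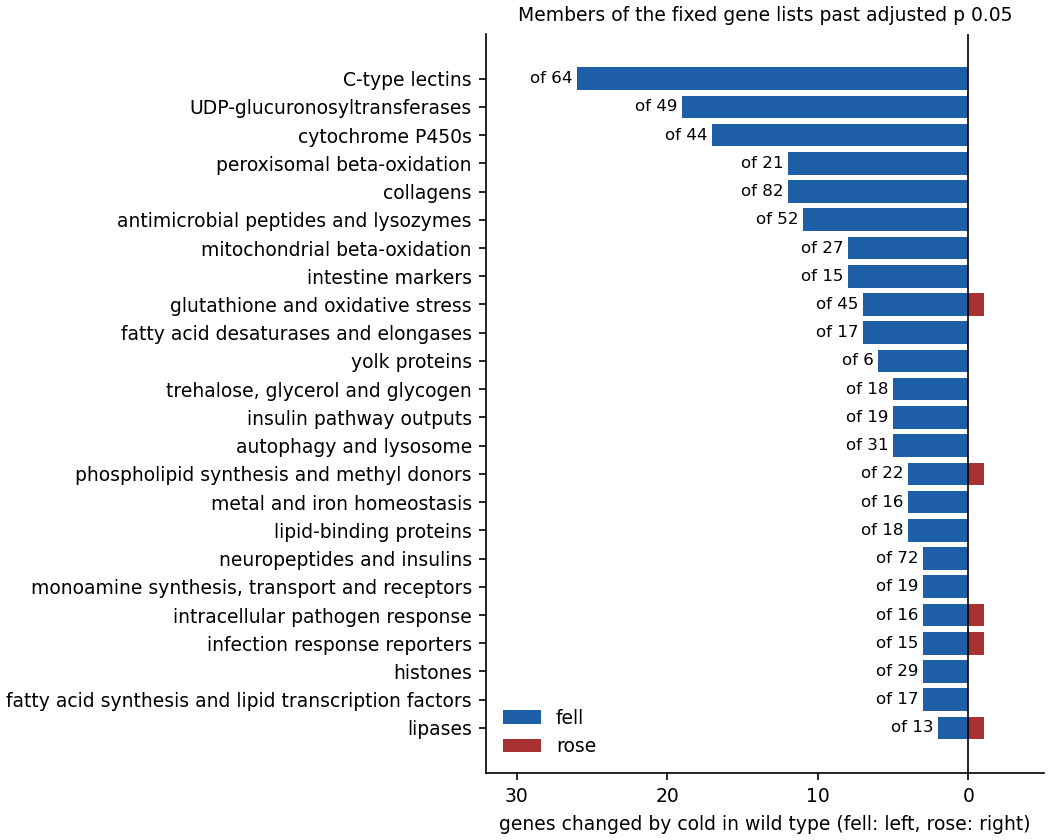
Number of genes that fell (left) or rose (right) in WT after cold in each fixed gene list with at least 3 genes past an adjusted p of 0.05, with the number tested. The C-type lectins had 26 of 64 genes lowered, the UDP-glucuronosyltransferases 19 of 49, the cytochrome P450s 17 of 44 and the peroxisomal beta-oxidation genes 12 of 21.

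The next comparison asked which genes cold changed in the ire-1 mutant (n = 3 per group, experiment 1). The 1545 calls in WT rest on n = 6 per group, so the counts of the 2 strains are not comparable. WT of experiment 1 fitted alone, with n = 3 per group, gave 3 genes. In the mutant 8 genes passed by edgeR, and all 8 rose. They were pqn-29 (6.51 ± 0.77, adjusted p = 0.0180), F19B10.13 (4.62 ± 0.53, adjusted p = 0.0173), kreg-1 (3.90 ± 0.41, adjusted p = 0.0173), K09D9.1 (3.21 ± 0.44, adjusted p = 0.0384), the gene ador-1 (3.05 ± 0.39, adjusted p = 0.0324), W09G12.7 (2.99 ± 0.40, adjusted p = 0.0384), W06H8.2 (2.82 ± 0.40, adjusted p = 0.0497) and C13G3.1 (2.81 ± 0.31, adjusted p = 0.0173). The transcript of kreg-1 went from 0.792 ± 0.303 to 11.9 ± 1.32 CPM, that of K09D9.1 from 5.36 ± 1.61 to 49.8 ± 12 CPM and that of C13G3.1 from 3.51 ± 0.664 to 24.7 ± 7.95 CPM (mean ± SD). Of these 8 genes 7 were tested in WT, and all 7 rose there too. Independent lists would share 0.189 genes, but genes vary together between libraries, so 0.189 is not a chance level for these 7. In WT their values were 5.79 ± 0.76 for pqn-29, 5.53 ± 0.46 for F19B10.13, 4.73 ± 0.61 for kreg-1, 3.70 ± 0.36 for K09D9.1, 2.90 ± 0.50 for W09G12.7, 2.33 ± 0.41 for W06H8.2 and 1.3 ± 0.28 for C13G3.1 (n = 6 per group).

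Several genes that changed in WT had values of the same sign in the mutant and did not pass there by edgeR, among them sbp-1 (-1.72 ± 0.28, adjusted p = 0.0778), acox-3 (-1.58 ± 0.27, adjusted p = 0.0878), srr-6 (5.28 ± 1.03, adjusted p = 0.106), zip-10 (2.25 ± 0.62, adjusted p = 0.225), ech-7 (-1.18 ± 0.26, adjusted p = 0.141) and clec-56 (-1.39 ± 0.36, adjusted p = 0.201). Without WT control 1 sbp-1, acox-3 and srr-6 passed (adjusted p = 0.0485 each), and srr-6 also passed without WT control 2 (adjusted p = 0.0101). The delta-9 desaturase genes fat-5 (-0.67 ± 0.43, adjusted p = 1.000), fat-6 (-0.79 ± 0.64, adjusted p = 1.000) and fat-7 (-0.16 ± 0.40, adjusted p = 1.000) did not pass, nor did hsp-3 (-0.34 ± 0.40, adjusted p = 1.000), hsp-4 (0.09 ± 0.35, adjusted p = 1.000), xbp-1 (0.15 ± 0.34, adjusted p = 1.000) and ire-1 itself (0.08 ± 0.25). Yolk genes had 0 of 6 below the threshold over all genes (3 fell adjusted over the list alone), with -1.43 for vit-1 and -1.24 for vit-3. Peroxisomal beta-oxidation had 0 of 21 (5 fell adjusted over the list alone), with -1.13 for acs-7. Genes of the intracellular pathogen response had 0 of 22 (5 fell adjusted over the list alone), with -3.49 for pals-31 and -2.41 for pals-17. Cold survival genes had 0 of 19 (3 rose adjusted over the list alone). UDP-glucuronosyltransferases (median -0.47, such as ugt-64 at -1.04) and cytochrome P450s (median -0.55, such as cyp-33C3 at -2.93) had none past the threshold, and 0 adjusted over the list alone. Camera gave adjusted p = 6.74e-09 for the yolk genes, which had an adjusted p = 0.940 with an estimated correlation. It gave 6.27e-06 for the peroxisomal list, 0.00159 for the pathogen list, 0.000974 for cold survival, 0.000567 for the glucuronosyltransferases, 0.000974 for the P450s and 1.34e-10 for 79 ribosomal proteins (median 0.20, 0 adjusted over the list alone). Each of these 6 had an adjusted p = 0.997 with an estimated correlation. The glucuronosyltransferase list did not pass without ire-1 control 1 (adjusted p = 0.156).

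Of 14344 genes tested in the mutant 1009 had an unadjusted p under 0.05, where chance gives 717 on average. Genes vary together between libraries, so such a count can lie far from 717 without any effect, here and below. Camera called 11 of 43 lists, 4 up and 7 down, while 0 passed with an estimated correlation (smallest adjusted p = 0.940 with an estimated correlation). Across 11250 genes the cold response of the mutant and that of WT in experiment 2 had r = 0.756 and rho = 0.701, where genes are not independent replicates. No call held in every leave-out: the count was 0 without ire-1 cold 1, ire-1 cold 3, ire-1 control 2 or ire-1 control 3, 2 without WT cold 3, 3 without WT cold 1 or WT cold 2, 4 without ire-1 cold 2 and 50 without WT control 1. DESeq2 called 342 genes, limma-voom 14, and edgeR 0 with a block for the replicate number.

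A direct test asked whether the cold response differed between ire-1 and WT within experiment 1 (n = 3 per group). No single gene passed, which does not show that the responses were equal. In the simulated data this test called 1.49% of genes with a 2-fold and 26.9% with a 4-fold difference. By edgeR 0 of 14344 genes were called (smallest adjusted p = 0.996), with 197 at an unadjusted p under 0.05, where chance gives 717. With WT and ire-1 libraries of the same number paired, 0 genes were called (smallest adjusted p = 0.504) and 836 had an unadjusted p under 0.05. DESeq2 called 1 gene and limma-voom 0. Of the genes given here, fat-5, fat-6, fat-7, hsp-3, hsp-4, xbp-1 and ire-1 are always given. The others were chosen after their values were seen. The cathepsin-like aspartyl protease gene asp-4 had a difference of 1.49 ± 0.35 (unadjusted p = 0.00155 by edgeR). It went from 539 ± 142 to 151.5 ± 37.3 CPM in WT and from 260.0 ± 44.7 to 205 ± 35.4 CPM in the mutant. The lysozyme gene lys-8 (1.59 ± 0.41) went from 124 ± 36.8 to 41.2 ± 16.35 CPM in WT and from 85.6 ± 9.72 to 85.3 ± 4.07 CPM in the mutant. Other genes with positive differences that did not pass were the protease genes asp-1 (1.62 ± 0.50) and cpl-1 (1.11 ± 0.34), the lysozyme genes ilys-5 (1.54 ± 0.44) and lys-4 (2.08 ± 0.66), the lectin genes clec-4 (1.89 ± 0.55) and clec-150 (1.11 ± 0.36), the intestinal genes pept-1 (1.17 ± 0.45), ges-1 (1.46 ± 0.59) and pgp-1 (1.56 ± 0.55), and mtl-2 (2.47 ± 0.99), a metallothionein gene. In fat metabolism the values were 1.37 ± 0.42 for daf-22, 0.48 ± 0.19 for let-767, 0.56 ± 0.61 for fat-5, 0.71 ± 0.90 for fat-6 and 0.86 ± 0.56 for fat-7, and none passed. In the ER they were 0.54 ± 0.57 for hsp-3, 0.51 ± 0.50 for hsp-4 and 0.19 ± 0.48 for xbp-1, which did not pass. The ire-1 transcript had -0.59 ± 0.36.

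Camera called 22 of 43 lists, 19 up and 3 down, while 0 passed with an estimated correlation (smallest adjusted p = 0.546 with an estimated correlation, for the intestine and metal lists). An upward value means that a list fell less or rose more in the mutant. The strongest was the antimicrobial list (65 genes, median 0.91, 58 above 0, 0 adjusted over the list alone), with an adjusted p = 9.46e-12 and an adjusted p = 0.637 with an estimated correlation. Intestine markers followed (16 genes, median 1.00, 15 above 0, 0 adjusted over the list alone), with an adjusted p = 2.02e-11 and an adjusted p = 0.546 with an estimated correlation. C-type lectins (95 genes, median 0.75, 76 above 0) had an adjusted p = 9.37e-07 and peroxisomal beta-oxidation (21 genes, median 0.54, 20 above 0) 1.36e-05, with 0 genes each adjusted over the list alone. Both of these lists had an adjusted p = 0.637 with an estimated correlation. These 4 and the metal list (16 genes, median 0.55, adjusted p = 0.00255, adjusted p = 0.546 with an estimated correlation) were the 5 of 22 that passed in each of the 12 leave-outs. Ribosomal proteins (79 genes, median 0.24, adjusted p = 1.33e-09, adjusted p = 0.666 with an estimated correlation) did not pass without ire-1 control 1 (0.251) or WT control 2 (0.679). With the strains paired by number the yolk genes passed (6 genes, median 0.45, adjusted p = 0.0299, adjusted p = 0.687 with an estimated correlation), where the adjusted p was 0.0818 without pairing. ER translocation (0.0967) and cold survival (0.134) did not pass with pairing. The median of all genes was 0.12 with TMM scaling, 0.02 with RLE and 0.22 with upper-quartile factors, and the list values are to be read against that.

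A cold score was made from experiment 2 alone, as the mean log2 CPM of its 10 raised genes minus that of its 38 lowered genes, and read in experiment 1. It was -5.2 ± 0.44 in WT control, 0.11 ± 0.18 in WT cold, -3.57 ± 0.59 in ire-1 control and 0.47 ± 0.25 in ire-1 cold (SD, n = 3 each). The shift was 5.30 in WT and 4.04 in ire-1. Their difference of -1.26 did not pass a two-sided exact permutation test (p = 0.175, 400 arrangements, smallest possible p = 0.005). Strain labels were exchanged within each condition, so the test also assumes equal scores of the strains in each condition. The score was higher in ire-1 in both, which widens the spread of the arrangements. This p therefore does not decide whether the shifts differ. With pairs of the same number moved between conditions, the exact p was 0.1, the smallest possible of 20 arrangements.

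**Figure D4:**
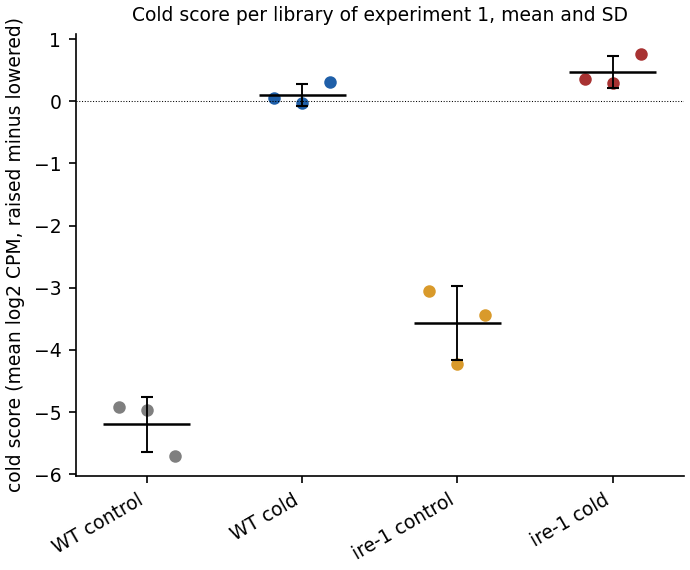
Cold score of each library of experiment 1 by group, with the mean and SD (n = 3 per group), where the score is the mean log2 CPM of 10 genes raised by cold minus that of 38 genes lowered by cold in WT of experiment 2. The score was -5.2 ± 0.44 in WT control, 0.11 ± 0.18 in WT cold, -3.57 ± 0.59 in ire-1 control and 0.47 ± 0.25 in ire-1 cold.

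The comparison of the strains in the control asked what the ire-1 mutation changed without cold (n = 3 per group). C38D9.2 (WBGene00008010, chromosome V, 17567150 to 17571742) was higher in the mutant by 8.15 ± 0.50 (adjusted p = 0.000107), at 86 ± 28.8 against 0.299 ± 0.151 CPM. F15D4.5 (WBGene00008862, chromosome II, 13245376 to 13247774) was higher by 4.91 ± 0.46 (adjusted p = 0.00341), at 24.8 ± 9.02 against 0.820 ± 0.421 CPM. The function of these 2 genes is not given in the sources used here. Lower in the mutant were pud-3 (-3.08 ± 0.38, adjusted p = 0.0238), the saposin-like genes spp-4 (-2.72 ± 0.39, adjusted p = 0.0455) and spp-5 (-1.79 ± 0.26, adjusted p = 0.0455), the cathepsin B-like gene cpr-9 (-2.28 ± 0.30, adjusted p = 0.0323), dod-23 (-2.17 ± 0.25, adjusted p = 0.0187), F23A7.4 (-2.04 ± 0.27, adjusted p = 0.0323) and the DNase II gene nuc-1 (-1.99 ± 0.25, adjusted p = 0.0238). The transcript of cpr-9 stood at 1766 ± 747 CPM in WT and 364 ± 45.1 CPM in the mutant, and that of nuc-1 at 168 ± 53 and 42.2 ± 3.05 CPM.

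By camera at a correlation of 0.01 several lists of antimicrobial, fat and ER genes shifted down in the mutant. Few or none of their genes passed singly, and none of the lists passed with an estimated correlation. Of 65 antimicrobial peptides and lysozymes 2 fell (11 adjusted over the list alone), with -1.78 for spp-3 and -1.83 for ilys-5 (neither past the threshold over all genes). Peroxisomal beta-oxidation had 0 of 21 (10 fell adjusted over the list alone), such as maoc-1 (-1.53 ± 0.26, adjusted p = 0.102), daf-22 (-1.71 ± 0.30, adjusted p = 0.110) and dhs-28 (-1.3 ± 0.27, adjusted p = 0.167). Fatty acid desaturases and elongases had 0 of 19 (4 fell adjusted over the list alone), with -1.66 for elo-6 and -0.59 for hpo-8, while fat-5 (-1.23 ± 0.44, adjusted p = 0.281), fat-6 (-0.61 ± 0.64, adjusted p = 0.791) and fat-7 (-1.29 ± 0.40, adjusted p = 0.234) did not pass. Yolk genes had 0 of 6 (3 fell adjusted over the list alone), with -1.23 for vit-1. Lipid-binding proteins had 0 of 18 (3 fell adjusted over the list alone), with -1.0 for lbp-6 and -1.78 for dsc-4. Intestine markers had 0 of 16 (5 fell adjusted over the list alone), with -1.43 for ges-1 and -1.42 for cpr-6. ER chaperones had 0 of 23 (1 fell adjusted over the list alone), with pdi-6 (-1.75 ± 0.41, adjusted p = 0.172), hsp-3 (-1.15 ± 0.41, adjusted p = 0.281) and hsp-4 (-0.84 ± 0.35, adjusted p = 0.362), while xbp-1 was at -0.16 ± 0.34. Camera gave adjusted p = 6.99e-07 for the antimicrobial list, 3.65e-08 for the peroxisomal list, 1.00e-05 for desaturases and for lipid-binding proteins, 3.27e-05 for yolk, 9.26e-05 for intestine and 0.000171 for ER chaperones. Each of these 7 had an adjusted p = 0.549 with an estimated correlation. The chaperone list did not pass without ire-1 control 1 (adjusted p = 0.0549). The values of hsp-3 and hsp-4 lean on WT control 1. It held 905 CPM of hsp-3 against 317 to 446 in the other WT controls, and 1066 of hsp-4 against 367 to 525. Without the 4 libraries with much sperm RNA hsp-4 was at 0.032, and without WT control 1 xbp-1 was at 0.35. The list of fatty acid synthesis and lipid transcription factors was higher (17 genes, median 0.25, 13 above 0, 0 adjusted over the list alone), with an adjusted p = 0.0122 and an adjusted p = 0.549 with an estimated correlation. It did not pass without WT control 1 (0.110) or ire-1 control 2 (0.0540). Germline and oocyte markers (34 genes, median 0.27, 29 above 0, 0 adjusted over the list alone) were also higher, with an adjusted p = 0.000903 and an adjusted p = 0.760 with an estimated correlation. Without WT control 1 their median was -0.0042 (adjusted p = 0.242). Pharynx markers (12 genes, median 1.17, 10 above 0, 0 adjusted over the list alone) had an adjusted p = 0.0340 and an adjusted p = 0.760 with an estimated correlation. They did not pass without WT control 1 (0.0755), 2 (0.142) or 3 (0.163), and without ire-1 control 1 their median was -0.084 (0.988). Sperm markers (53 genes, median 0.08, 0 adjusted over the list alone) had an adjusted p = 0.0340 and an adjusted p = 0.906 with an estimated correlation, which did not pass without ire-1 control 1 (0.0931), WT control 2 (0.642) or WT control 3 (0.760). Their median turned to -3.38 without ire-1 control 1 and to -0.14 without WT control 2. Leaving out ire-1 control 1 alone keeps WT control 1, which also held much sperm RNA. By replicate number, the mean log2 CPM of the sperm genes in ire-1 was 4.44 against 4.30 in WT, -0.26 against -1.58 and -0.24 against -1.94.

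Some of these genes passed in the control once WT and ire-1 libraries of the same number were paired. The pairing was read from these same data and may rest on the libraries with much sperm RNA, so these calls are tentative. They were spp-3 (adjusted p = 0.00878), ilys-5 (0.00558), maoc-1 (0.0056), daf-22 (0.0078), dhs-28 (0.0146), elo-6 (0.0365), fat-7 (0.0248), lbp-6 (0.0224), dsc-4 (0.0161), ges-1 (0.0401), cpr-6 (0.0056) and pdi-6 (0.0401). Without pairing, spp-3 (0.0211), daf-22 (0.0331) and ilys-5 (0.0474) passed without WT control 3, and maoc-1 without WT cold 1 (0.0432). The body wall muscle list (24 genes) passed with pairing (median 0.05, adjusted p = 0.0184, adjusted p = 0.720 with an estimated correlation) and not without it (adjusted p = 0.164).

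In the control edgeR called 9 of 14344 genes, 2 up and 7 down, DESeq2 296 and limma-voom 9. By edgeR 1742 genes had an unadjusted p under 0.05, where chance gives 717 on average but with a wide spread, as genes vary together. With WT and ire-1 libraries of the same number paired, edgeR called 390 genes, 89 up and 301 down, among them all 9. Camera called 21 of 43 lists, 4 up and 17 down, of which 9 passed in each leave-out, and 0 passed with an estimated correlation. The 2 raised genes kept their calls in each of the 12 leave-outs and the 7 lowered genes did not. The count was 2 without any of the 3 ire-1 control libraries or without WT control 2, 4 without WT control 1, WT cold 2, WT cold 3 or ire-1 cold 1, 5 without ire-1 cold 2 or 3, and 48 without WT control 3.

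The last comparison asked how the strains differed after cold (n = 3 per group). The same 2 genes were higher in the mutant, C38D9.2 (6.93 ± 0.47, adjusted p = 0.000289) and F15D4.5 (3.85 ± 0.43, adjusted p = 0.0211). Over both conditions C38D9.2 lay between 42.3 and 124 CPM in the 6 ire-1 libraries and between 0 and 0.669 CPM in the 12 WT libraries. F15D4.5 lay between 17.8 and 36.6 CPM in the mutant and between 0.474 and 1.71 CPM in WT. No other gene passed by edgeR. The saposin-like genes that were lower in the control had -1.58 ± 0.38 for spp-4 and -0.84 ± 0.25 for spp-5 in the cold, and did not pass. The glucuronosyltransferase gene ugt-64 (-1.51 ± 0.29, adjusted p = 0.443), the lectin gene clec-4 (1.87 ± 0.40, adjusted p = 0.546) and the lysozyme gene lys-8 (1.05 ± 0.29, adjusted p = 0.613) did not pass. With the strains paired by number ugt-64 passed at -1.49 (adjusted p = 0.0209) and the collagen gene sqt-3 at 2.53 (adjusted p = 0.0169). In the fat genes the values were -0.67 ± 0.43 for fat-5, 0.10 ± 0.63 for fat-6 and -0.42 ± 0.40 for fat-7, and in the ER -0.61 ± 0.41 for hsp-3, -0.33 ± 0.35 for hsp-4 and 0.03 ± 0.34 for xbp-1, all past no threshold. The abu genes, which were named for their activation when ER stress signalling is blocked, had 0 of 3 past the threshold over all genes (2 rose adjusted over the list alone), with abu-14 (2.93 ± 0.72, adjusted p = 0.613) and abu-12 (3.27 ± 1.12, adjusted p = 0.613). Yolk genes had 0 of 6 (1 fell adjusted over the list alone), with -1.16 for vit-1 and -1.02 for vit-4. Collagens had 0 of 126 (1 rose adjusted over the list alone), with 2.56 for sqt-3 and 2.63 for dpy-3. Pharynx markers had 0 of 12 (0 adjusted over the list alone), with 3.95 for myo-2 and 1.1 for pha-4. Camera gave the abu genes an adjusted p = 0.000913 and an adjusted p = 0.612 with an estimated correlation. It gave 0.00246 for yolk, 0.00236 for collagens and 0.000913 for the pharynx, and each of these 3 had an adjusted p = 0.992 with an estimated correlation. The yolk list did not pass without WT cold 1 (adjusted p = 0.669), and the pharynx list did not pass without ire-1 cold 2 (adjusted p = 0.196). Without the 4 libraries with much sperm RNA the collagen median turned from 1.54 to -0.16.

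Sperm markers were higher in the mutant in the cold (53 genes, median 1.66, 52 above 0, 0 adjusted over the list alone), with an adjusted p = 0.00431 and an adjusted p = 0.992 with an estimated correlation. They did not pass without WT cold 1 (0.308), WT cold 3 (0.0554) or ire-1 cold 2 (0.113), and their median turned to -2.66 without ire-1 cold 2 and to -0.18 with the sperm-gene level as a covariate. Leaving out ire-1 cold 2 alone keeps WT cold 2, which also held much sperm RNA. By replicate number, the mean log2 CPM of the sperm genes in ire-1 was -1.06 against -1.89 in WT, 4.08 against 2.34 and -0.55 against -0.72. Body wall muscle markers (24 genes, median 0.39, 22 above 0, 0 adjusted over the list alone) had an adjusted p = 0.0436 and an adjusted p = 0.992 with an estimated correlation. They did not pass without WT control 2 (0.0522), WT cold 1 (0.320), WT cold 3 (0.197) or ire-1 cold 2 (0.991), and the median turned to -0.34 without ire-1 cold 2.

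In the cold edgeR called 2 of 14344 genes (1098 at an unadjusted p under 0.05, where chance gives 717), DESeq2 46 and limma-voom 2. With the strains paired by number it called 22 genes, 9 up and 13 down, among them both. Camera called 11 of 43 lists, 7 up and 4 down (0 with an estimated correlation). The call of C38D9.2 held in each leave-out. That of F15D4.5 was lost without WT cold 1 (adjusted p = 0.160), 2 (0.196) or 3 (0.178), ire-1 cold 1 (0.0644), 2 (0.0612) or 3 (0.113), or ire-1 control 3 (0.0658). The count was 3 without WT control 1 or 3.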

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

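Of the tests in this part, only the comparison of ire-1 control with the WT cold pattern was chosen before its result was seen, and the other tests were chosen after the results were seen.

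A library lay far from the 5 others of its WT group in 13 of the 62 values tested (gap divided by range above the 95% critical value of Dixon's test), where chance gives about 1 in 20 groups, or 3.1. In WT control 1 these were F22F7.8 (0.685, 39.5 CPM against 4.82 to 9.54), anmt-3 (0.674), asp-13 (0.725, 93.5 CPM against 154 to 187), ugt-63 (0.638), fat-7 (0.635, 173 CPM against 56.8 to 85.4), hsp-3 (0.675), hsp-4 (0.665, 1066 CPM against 367 to 525) and xbp-1 (0.683). In WT cold 5 they were F19B10.13 (0.755), F33H12.7 (0.670), W06H8.2 (0.676) and kreg-1 (0.788, 36.5 CPM against 6.27 to 9.21), and in WT control 6 Y58A7A.4 (0.635).

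The first pattern is that 4 libraries, control 1 and cold 2 of both strains, held 492 to 2130 CPM of sperm genes. Exchanged condition labels were excluded, as 0 of the 4 had a cold score nearer the other condition (means of the other libraries 0.37 in the cold and -4.58 in the control). Exchanged strain labels were excluded, as 0 of the 4 had an ire-1 level in the range of the other strain. More young or male worms in these samples may be the source: 2 of the 4 had a yolk share below both others of their group, which leaves it open. In each of the 4, germline markers lay below both others of the group, such as 7.11 against 8.89 and 8.74 in WT control 1 (mean log2 CPM). The gap was small in WT cold 2 (8.596 against 9.243 and 8.603). Muscle, intestine, collagen and neuron sets lay above both others in each. A smaller share of germline RNA is therefore a candidate for part of the pattern. Sperm genes rose far more than the muscle set, which argues against that share alone as the source of the sperm-gene level. The sperm genes had 4.30 in WT control 1 against -1.58 and -1.94, and 4.44 in ire-1 control 1 against -0.26 and -0.24. They had 2.34 in WT cold 2 against -1.89 and -0.72, and 4.08 in ire-1 cold 2 against -1.06 and -0.55. The muscle set had 8.33 against 7.23 and 6.41 in WT control 1, and 8.61 against 7.28 and 7.30 in ire-1 cold 2.

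The second pattern is that 22 lists differed in their cold response between ire-1 and WT by camera while edgeR called 0 genes (197 at an unadjusted p under 0.05 where chance gives 717, 836 with the strains paired, 1 by DESeq2, 0 by limma-voom). Their medians were 0.42 for ER chaperones, 0.14 for ER translocation, 0.53 for desaturases and elongases, 0.45 for mitochondrial and 0.54 for peroxisomal beta-oxidation, 0.51 for lipid-binding proteins, 0.31 for cold survival, 0.67 for insulin outputs, 0.53 for cytochrome P450s, 0.71 for UDP-glucuronosyltransferases, 0.75 for C-type lectins, 0.91 for antimicrobial peptides, 0.70 for infection reporters, 0.55 for metal homeostasis, -0.11 for the proteasome, 0.24 for ribosomal proteins, 0.19 for oxidative phosphorylation, 1.2 for collagens, 0.52 for neuropeptides, 1.00 for intestine, -0.23 for germline and -0.19 for eggshell. Genes of a list that vary together between libraries are a candidate explanation, since 0 lists passed with an estimated correlation. The 4 libraries with much sperm RNA could account for part, as 11 of the 22 lists passed in the same direction without them. Chance was not excluded, since 13 of 100 splits gave as many lists (real 22, highest other 27).

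The third pattern is that C38D9.2 and F15D4.5 were higher in ire-1 in both conditions. A single library was excluded for C38D9.2, with 0 calls lost in 12 leave-outs in each condition. A variant at C38D9.2 itself that is linked to ire-1 was excluded, since only 1 gene of the pair C38D9.2 and ire-1 lies on chromosome II. A linked variant that acts on C38D9.2 from a distance and an unlinked variant of the strain were not tested. For F15D4.5, which lies 5.12 Mb from ire-1 on the same chromosome, a linked variant may be the cause and stays open. An effect of the mutation itself is a hypothesis that a rescue of ire-1 or a second allele would test.

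The next pattern is that exchanging WT control 6 and WT cold 5 called 3697 genes, more than the real 1545, which points to a structure of the samples. Across 11766 genes, which are not independent replicates, their deviations from the other libraries of their groups in experiment 2 had r = -0.765. Exchanged condition labels were excluded, as 0 of the 2 lay nearer the other condition in the mean log2 CPM of the 8 genes raised by cold in ire-1. This mean was -0.38 in WT control 6 against 0.15 and 0.14 in the other controls, and 4.40 in WT cold 5 against 2.57 and 2.68 in the other cold libraries. Another share of germline RNA is a candidate explanation: in 2 of 2 libraries germline markers lay beyond both others of the group and muscle, intestine, collagen and neuron sets lay beyond them the other way. The lists called for cold in WT include germline, intestine and collagen genes, so part of their shift could come from such a share, and counts from whole worms leave this open. Without both libraries 3395 genes and 18 lists were called.

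The control difference between ire-1 and WT and the cold response of WT in experiment 2 had r = 0.375 (rho 0.475) across 11282 genes, which are not independent replicates, and 41 of 48 called genes had the same sign. The 10 splits of the 6 control libraries are too few for a share under 0.05 (highest other r 0.350, highest other rho 0.555, and 44 of 48 with the same sign in another split). The real split therefore had the highest r but not the highest rho or count of same signs.

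For cold in WT 2 of 100 splits gave as many genes, the real one among them (real 1545, highest other 3907). These 100 were drawn from 462 splits that cross the experiments. Of 100 splits within each experiment, drawn from 200, 3 gave as many, the real one among them (real 1545, highest other 3697). Both others exchanged WT control 6 with WT cold 5. These shares lie under 0.05, a limit set after the results were seen. Other splits called more genes than the real one, so the count also follows the structure of the samples. Chance is therefore not strictly excluded. For the lists in WT chance was not excluded, with 62 of 100 splits (real 15, highest other 26) and 65 of 100 within each experiment. For the difference in cold response the splits say nothing about chance, since any of them gives at least the real 0 genes (100 of 100, highest other 4672). The 10 splits of 3 against 3 libraries are too few for a share under 0.05. Their real values and highest others were 8 and 0 genes for cold in ire-1 (1 split as large), 9 and 0 for the strains in the control (1 split) and 2 and 0 in the cold (1 split). For lists they were 11 and 21 for cold in ire-1 (7 splits), 21 and 20 in the control (1 split) and 11 and 24 in the cold (9 splits). Among the 4 splits that part all 3 pairs of WT and ire-1 libraries, the others gave at most 0 genes in each condition, and at most 18 lists in the control and 23 in the cold.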

How the results depend on the processing

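Some separate fits were chosen after the data were seen. They left out the 4 libraries with much sperm RNA, used the sperm-gene level as a covariate, or used an indicator for those libraries. Others used a replicate block within each condition, or left out WT control 6 and WT cold 5. The other alternatives were planned. The cause of a change was not tested unless a sentence says so.

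With DESeq2 the gene counts were 2611 for cold in WT, 342 for cold in ire-1, 1 for the difference in cold response, 296 for the strains in the control and 46 in the cold. For cold in WT experiment 1 alone gave 3 genes, experiment 2 alone 48, the covariate 2711 and the fit without WT control 6 and WT cold 5 3395. For cold in ire-1 the count was 17 with RLE, 4 with upper-quartile factors, 0 with the replicate block, 14 with limma-voom, 102 over 18 libraries, 0 with 2 groups alone, 187 without the 4 libraries, 703 with the covariate and 597 with the indicator. For the strains in the control it was 2 with the block, 47 over 18 libraries, 1 with 2 groups alone, 3 without the 4 libraries, 2325 with the covariate and 620 with the indicator. For the strains in the cold it was 5 over 18 libraries, 6 without the 4 libraries, 28 with the covariate, 16 with the indicator and 3 with upper-quartile factors. With the replicate block within each condition, which pairs the strains by number, the strains in the control gave 390 genes and those in the cold 22, and fat-6 in the cold turned to -0.093. Beyond the genes and lists given in the text, myo-1, myo-2, vit-3, vit-4, cdr-6, clec-50, clec-150 and cyp-35A5 gained a call in the control, and no other call of a named gene or list changed. The cold score difference had an exact p = 0.344 with labels exchanged within pairs and 0.1 with pairs moved between conditions (20 arrangements, smallest possible 0.1). With an estimated correlation 0 lists passed in each of the 5 comparisons. Cold in ire-1 gave 7 lists with the covariate, and the strains in the cold 7 without the 4 libraries and 6 with the covariate.

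Leaving out 1 library gave 848 (without WT control 5) to 2632 (without WT control 6) genes for cold in WT, with 867 without WT cold 1, 886 without WT control 4, 892 without WT cold 4, 966 without WT cold 6 and 987 without WT cold 3. For cold in ire-1 it gave 0 (without ire-1 cold 1 or 3 or ire-1 control 2 or 3) to 50 (without WT control 1), with 2 without WT cold 3, 3 without WT cold 1 or 2 and 4 without ire-1 cold 2. The strains in the control gave 2 (without any ire-1 control library or WT control 2) to 48 (without WT control 3), with 4 without WT control 1, WT cold 2, WT cold 3 or ire-1 cold 1 and 5 without ire-1 cold 2 or 3. The strains in the cold gave 1 (without WT cold 1 or 3, any ire-1 cold library or ire-1 control 3) to 3 (without WT control 1 or 3). For lists, cold in ire-1 gave 8 (without WT control 2) to 17 (without ire-1 cold 2).

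Signs turned for these genes, none of which had passed. For cold in WT hsp-4 (-0.14) was 0.22 in experiment 2 alone and 0.17 without the 2 WT libraries with much sperm RNA, and -0.23 to 0.19 in the leave-outs. For cold in ire-1 the leave-outs gave -0.40 to 0.145 for fat-7, -0.12 to 0.21 for hsp-4, -0.090 to 0.22 for ire-1 and -0.015 to 0.52 for xbp-1, and hsp-4 was -0.00511 without the 4 libraries. For the difference in cold response they gave -0.14 to 1.22 for fat-6, -0.20 to 0.82 for hsp-3, -0.092 to 0.78 for hsp-4 and -0.25 to 0.42 for xbp-1. Without the 4 libraries it was -0.0680 for fat-6, -0.052 for hsp-3 and -0.15 for hsp-4, and xbp-1 was -0.045 over 18 libraries. For the strains in the control the leave-outs gave -1.04 to 0.30 for fat-6 and -0.40 to 0.35 for xbp-1, hsp-4 was 0.032 without the 4 libraries, and xbp-1 was 0.032 with RLE, 0.013 without a filter, 0.032 with DESeq2 and 0.012 over 18 libraries. In the cold fat-6 was -0.089 with limma-voom, -0.0189 over 18 libraries, -0.42 without the 4 libraries, -0.37 with the covariate, -0.13 with the indicator and -0.65 to 0.39 in the leave-outs, and xbp-1 was -0.033 over 18 libraries, -0.10 with the covariate and -0.10 to 0.16 in the leave-outs.

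List medians also turned. In the leave-outs they were -0.047 to 0.33 (germline) and -0.037 to 0.23 (proteasome) for cold in ire-1. For the difference in cold response they were -0.93 to 2.15 (collagens), -0.051 to 0.39 (ribosomal), -0.51 to 0.054 (eggshell), -0.61 to 0.089 (germline) and -0.40 to 0.053 (proteasome), with -0.11 for collagens and 0.0060 for eggshell without the 4 libraries. For the strains in the control they were -0.29 to 0.20 (ribosomal), -0.0042 to 0.64 (germline), -0.084 to 1.71 (pharynx) and -3.38 to 6.33 (sperm). For the strains in the cold they were -0.34 to 0.84 (body wall muscle), -0.64 to 2.04 (collagens), -0.35 to 0.68 (neuropeptides) and -2.66 to 4.73 (sperm), with -0.16 for collagens without the 4 libraries and -0.18 for sperm with the covariate.

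Of the values of single genes under the alternatives, 2604 of 3103 gave the same call for cold in WT, 483 were weaker and 13 stronger. For cold in ire-1 567 of 712 were the same, 81 weaker and 57 stronger. The difference in cold response had 520 of 529 the same. The strains in the control had 725 of 912 the same, 85 weaker and 94 stronger, and those in the cold 560 of 597 the same, 7 weaker and 17 stronger. Of the values of single lists for cold in WT 16 of 300 were weaker and the others the same. Single lists gave the same call in 160 of 209 (ire-1), 351 of 440 (difference), 357 of 420 (control) and 170 of 220 (cold), and were weaker in 47, 80, 58 and 44. Experiment 2 was sequenced to 10449794 to 16814732 counts and experiment 1 to 20621965 to 29518450.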

Other observations

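The leave-outs and fits without the 4 libraries with much sperm RNA named here were chosen or read after the results were seen.

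The 7 genes that rose after cold in both strains, pqn-29, F19B10.13, kreg-1, K09D9.1, W09G12.7, W06H8.2 and C13G3.1, stood at low levels in the control. C13G3.1 had the largest gap between the strains, with 2.81 in ire-1 and 1.3 in WT, and the direct test in experiment 1 gave a difference of 1.76 (unadjusted p = 0.00146 by edgeR, which did not pass after adjustment).

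The cold score of ire-1 control lay nearer to the cold libraries than that of WT control (-3.57 ± 0.59 against -5.2 ± 0.44, SD, n = 3 each), while the cold scores were 0.47 ± 0.25 and 0.11 ± 0.18. In 6 of 6 pairs of the same number and condition the score was higher in ire-1, by 1.86, 0.75 and 2.27 in the control and 0.31, 0.33 and 0.46 in the cold. The difference in shift was -1.26 (exact permutation p = 0.175), -1.11 without the 4 libraries with much sperm RNA and -1.58 (without ire-1 control 2) to -0.99 (without ire-1 control 1) in the leave-outs. The raised genes stood at 1.57 in ire-1 control and 0.50 in WT control (mean log2 CPM), and the lowered genes at 5.14 and 5.69. The difference was -0.74 with the raised genes alone and -0.52 with the lowered genes alone. None of the 18 libraries is of worms kept 24 h longer at 15 °C, so age and cold cannot be separated here.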
